A study of Mus musculus with 19 samples.

How the data were processed

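RNA was measured on Affymetrix mouse arrays in 7 angiosarcomas, 4 aortas, 4 quadriceps femoris muscles and 4 sternocleidomastoid muscles, 1 array per sample. Per the labels, RNA was extracted with the Qiagen miRNeasy mini kit, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with standard Affymetrix protocols. The deposited values were read as log2 intensity, because they ran from 1.6 to 14 with no negative values and array medians of 5.4 to 5.5. The labels name Partek 6.6 among the processing tools, but its role and the normalization of the values are not given in the sources used here. The sorted values of the arrays differed by at most 0.43 log2 units (median gap 0.14), as after a normalization between arrays, and no further scaling was applied in the principal results.

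The table held 41345 probe sets, of which 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none in the platform's annotation. Only single-symbol probe sets were tested, and for the 1082 genes with more than 1 of them the probe set with the highest mean over the 19 arrays was used, which left 22180 genes. Of these 1082 genes, 7 had probe sets with opposite calls in the tumor and aorta comparison and 41 in the tumor and muscle comparison. Trp53, Igf2bp1 and Igf2bp2 had no single-symbol probe set. Gene positions were used only to define neighbouring genes, and no coordinates are given because the annotation's genome build was not stated for the arrays.

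Groups were taken from the labels, which give no batch, sex, age or animal identity. A model with 1 mean per group (tumor, aorta, quadriceps and sternocleidomastoid) was fitted to all 19 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. The contrasts were tumor minus aorta, tumor minus the mean of the muscle groups, and sternocleidomastoid minus quadriceps, and a gene was counted against both tissues when it passed in the same direction in both tumor contrasts. Gene lists (40 tested, at least 5 measured genes each) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 120 tests, and members were also adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

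The design, gene lists, named genes and alternatives were fixed before the data were examined. The named genes were Dicer1, a fixed set given as values, the 8 largest increases and decreases in each tumor comparison among genes past the threshold whose groups did not overlap, and the 6 largest for both tissues (by the smaller of the 2 absolute differences) and for the muscles. Riken, Gm-numbered and predicted names were left out of that ranking. In each list described, the 2 to 4 members with the largest absolute difference past the threshold were named, or the 2 largest where none passed.

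The alternatives were centring arrays on the median gene or on the housekeeping list, quantile normalization, leaving out dim genes, the mean over a gene's probe sets, eBayes with trend and robust options, 1 variance per group, the arrays of the compared groups only, a threshold of 0.01, a minimum 2-fold difference, each muscle alone, and leaving out each array in turn. For lists they were an estimated correlation, the fry directional test, the centrings and the mean over probe sets. Further alternatives used subsets of tumors or aortas and were chosen after seeing the data.

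The pipeline was tested on simulated data built from 22180 genes with 50 changed genes of each size. In the tumor and aorta comparison it recovered 56% of changes of 0.5 log2 units, 88% of changes of 1 and 98% of changes of 2, with 11 false calls. In the tumor and muscle comparison it recovered 58%, 98% and 100% with 5 false calls, and between the muscles 42%, 84% and 100% with 8. With unchanged data camera called 0 of 120 tests. The simulated genes varied independently, whereas the estimated correlation among general adipocyte genes was 0.864 in the arrays. That result therefore does not cover false list calls among correlated genes. The number of arrays limits the precision.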

Results

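Gene expression was measured on 19 Affymetrix arrays, each hybridised with labelled RNA from a mouse sample of mixed C57Bl/6 and 129X1/SvJ strain background. The samples were 7 angiosarcomas, malignant tumors of endothelial lineage, together with 4 normal aortas, 4 quadriceps femoris muscles and 4 sternocleidomastoid muscles. The tumors came from animals carrying Cre recombinase under the aP2 (Fabp4) promoter, 1 floxed Dicer allele and 1 null Dicer allele. The normal tissues came from wild type animals, so tissue and genotype changed together in every tumor comparison. Array medians lay between 5.4 and 5.5 log2 units and values between 1.6 and 14. The number of arrays limited the precision of each comparison. Because the labels did not say which samples came from separate animals, p-values measured only the spread between these samples.

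Tumors, aortas and muscles formed separate clusters in a principal component analysis of the 22180 genes tested. The first component held 56.0% of the variance and placed the tumors at -82.8 to -56.8, the aortas at -9.95 to -0.47 and the muscles at 54.1 to 67.5. Along the second component, with 21.2% of the variance, the tumors were spread from -26.0 in tumor 5 to 43.7 in tumor 2. Median gene-wise SD was 0.21 log2 units among tumors, against 0.16 among aortas, 0.14 among quadriceps and 0.16 among sternocleidomastoid samples.

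**Figure D1:**
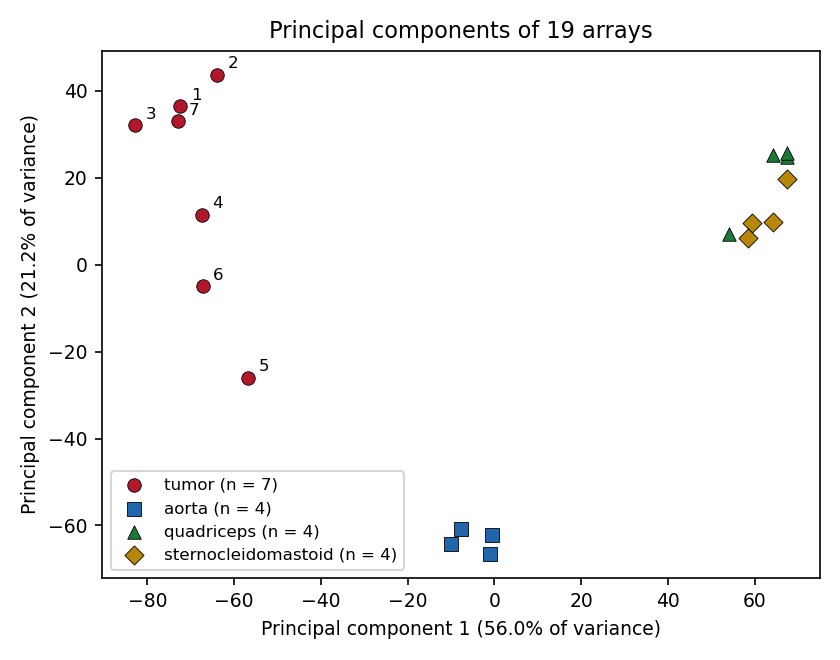
Scores of the 19 arrays on principal component 1 (horizontal, 56.0% of the variance) and component 2 (vertical, 21.2%) of the log2 intensities of 22180 genes, 1 point per array and tumors numbered. Tumors lie at -82.8 to -56.8 on the horizontal axis and muscles at 54.1 to 67.5, while tumor 5, at -26.0 on the vertical axis, is the tumor nearest the aortas.

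Dicer1, the RNase that cuts microRNA precursors and the gene targeted in the tumor-bearing animals, had a similar signal in tumors and normal tissue. Its mean log2 intensity was 8.53 ± 0.26 (SD, n = 7) in tumors, 8.23 ± 0.16 (n = 4) in aorta, 8.76 ± 0.14 (n = 4) in quadriceps and 8.42 ± 0.10 (n = 4) in sternocleidomastoid. The tumor minus aorta difference was 0.29 ± 0.12 (SE; limma adjusted p = 0.0714) and the tumor minus muscle difference was -0.06 ± 0.10 (adjusted p = 0.629). Leaving out tumor 2 or tumor 7 gave a difference from aorta of 0.35 that passed the threshold (adjusted p = 0.0213 and 0.0242), as did leaving out tumors 2 and 5, a subset chosen after seeing the data (0.32, adjusted p = 0.0416). Centring arrays on the housekeeping list gave -0.16 against aorta (adjusted p = 0.281) and -0.63 against muscle (adjusted p = 3.74e-05). The position of the Dicer1 probes relative to the floxed exon was not given in the sources used here, so these values check nothing about the deletion.

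The tumor and aorta comparison asked how the angiosarcomas differed from a normal vessel. Most measured members rose among pan-endothelial markers (29 of 32), sprouting genes (18 of 20), mitotic genes (31 of 31), proteases (15 of 20), macrophage markers (21 of 22) and platelet genes (8 of 9), while smooth muscle (13 of 20), heart muscle (12 of 14), general adipocyte (17 of 19), brown adipocyte (13 of 14) and oxidative phosphorylation genes (28 of 29) mostly fell. Of these list calls only that of heart muscle held with an estimated correlation (adjusted p = 0.0215), and the others were lost (adjusted p = 0.0608 to 0.606 with an estimated correlation). The endothelial adhesion molecules Pecam1 and Cdh5 rose 3.56-fold and 3.87-fold, and the proliferation marker Mki67 rose 7.80-fold. The atrial myosin light chain Myl7 was at least 125-fold lower, a lower bound because its tumor mean of 4.36 lay below the median of every array.

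The 8 genes with the largest increases over aorta included Prnd, the prion-like protein doppel (log2 difference 5.13 ± 0.32), the imprinted gene Mest (5.09 ± 0.28), the inflammatory cytokine Il1b (4.46 ± 0.35) and the matricellular protein Thbs1 (4.27 ± 0.31). The others were the apelin receptor Aplnr (4.10 ± 0.37), the G-protein regulator Rgs16 (4.02 ± 0.31), the protease inhibitor Tfpi2 (4.01 ± 0.40) and Plvap, a diaphragm protein of fenestrated endothelium (3.85 ± 0.20). The 8 largest decreases were in Myl7 (-6.97 ± 0.13), the thermogenic uncoupling protein Ucp1 (-6.35 ± 1.21), the fatty acid elongase Elovl3 (-5.63 ± 0.45) and the lipid droplet protein Cidea (-5.54 ± 1.02). They continued with the calcium pump regulator Pln (-5.36 ± 0.17), the cardiac myosin heavy chain Myh6 (-5.20 ± 0.14), the fatty acid transporter Slc27a2 (-5.17 ± 0.39) and the integrin chain Itga8 (-5.0 ± 0.26). As their selection required, all 7 tumors lay beyond all 4 aortas for each of these 16 genes, with adjusted p from 2.7e-17 for Myl7 to 0.000337 for Ucp1. Tumor means of Myl7, Elovl3, Pln, Myh6 and Slc27a2, and aorta means of Il1b (3.98) and Rgs16 (5.10), lay below the median of every array, so their differences and ranks are limited by dim signal. A second, dimmer probe set differed from aorta by 0.105 for Prnd (limma adjusted p = 0.464) and by -0.568 for Slc27a2 (0.00132).

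Of 32 pan-endothelial markers, 29 rose in tumors (30 adjusted over the list alone) and 0 fell, with a median difference of 1.72. Plvap led them, with the C1q receptor family member Cd93 (2.84 ± 0.18) and the tight junction protein Cldn5 (2.34 ± 0.26). The call (camera adjusted p = 4.13e-19) was lost with an estimated correlation (adjusted p = 0.134). The arrays measured RNA of tissue samples. For this and the other lists, a different share of a cell type therefore cannot be told apart from a change within that cell type. Tip cell and sprouting genes rose in 18 of 20 cases (18 adjusted over the list alone), led by Aplnr, its ligand Apln (3.65 ± 0.20), the urokinase receptor Plaur (3.51 ± 0.32) and the growth factor Pgf (3.13 ± 0.35, with a dim aorta mean of 4.99). Here the median was 1.69 and the camera adjusted p was 8.87e-12, against adjusted p = 0.0608 with an estimated correlation. Among 11 lymphatic endothelial markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), including the lymphatic growth factor receptor Flt4 (2.39 ± 0.23) and the scavenger receptor Stab2 (1.99 ± 0.32). That list's camera adjusted p was 0.0173, and adjusted p = 0.126 with an estimated correlation. In the Notch pathway 12 of 18 genes rose and 2 fell (13 and 2 adjusted over the list alone): the feedback inhibitor Nrarp rose by 2.27 ± 0.19 and the ligand Dll1 by 1.87 ± 0.10, while the transcriptional repressor Hey2, an effector of the pathway, fell by 2.04 ± 0.23. Its camera adjusted p was 3.04e-05, and adjusted p = 0.115 with an estimated correlation.

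Among 17 measured genes of the angiosarcoma-linked list, 15 rose and 0 fell (16 adjusted over the list alone), and the call held with an estimated correlation (camera adjusted p = 3.86e-07 and 0.0225). Flt4 led the list, followed by the transcription factor Myc (2.04 ± 0.31), the immediate early gene Fos (1.83 ± 0.41) and the endothelial growth factor receptor Kdr (1.76 ± 0.22). The list median of 0.45 became -0.001 when arrays were centred on the housekeeping list. Cdkn2a, which encodes the tumor suppressors p16 and p19Arf, had means of 6.41 ± 0.36 (SD) in tumors and 5.98 ± 0.20 in aortas (adjusted p = 0.0524). It passed the threshold when arrays were centred on the median gene (adjusted p = 0.047), with dim genes left out (0.0365), with 1 variance per group (0.0458) and without tumor 2, tumor 5 or aorta 3 (0.0291, 0.0296 and 0.0448). It also did so with tumors 1 to 4 alone (0.0341) and without tumors 2 and 5 (0.0112), subsets chosen after seeing the data. Its difference was -0.017 when arrays were centred on the housekeeping list. Trp53 was not analysed here because no probe set carried its symbol alone.

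Smooth muscle contractile genes fell in 13 of 20 cases and rose in 0 (14 fell adjusted over the list alone), with a median of -1.03. Pln and Itga8 fell most, followed by calponin, Cnn1 (-2.96 ± 0.37), and the smooth muscle myosin Myh11 (-2.86 ± 0.31). The list's camera adjusted p was 6.55e-07, and adjusted p = 0.114 with an estimated correlation. Elastic matrix genes of large arteries went both ways, with 4 of 13 rising and 5 falling (4 and 8 adjusted over the list alone; camera adjusted p = 0.464): elastin, Eln, fell by 1.87 ± 0.45 and its crosslinking enzyme Lox rose by 1.66 ± 0.48. The Lox call was lost without aorta 4 (1.38, adjusted p = 0.0514), and that of Eln without aortas 1 and 3, chosen after seeing the data (-1.44, adjusted p = 0.0862). Fibrillar collagen and stromal matrix genes rose in 16 of 19 cases (17 adjusted over the list alone), led by Col12a1 (3.21 ± 0.45), tenascin C, Tnc (2.87 ± 0.43), and Thbs2 (2.59 ± 0.34). The collagen list had a camera adjusted p of 1.99e-08, and adjusted p = 0.241 with an estimated correlation. Matrix proteases and plasminogen system genes rose in 15 of 20 cases (15 adjusted over the list alone), including the metalloproteinase inhibitor Timp1 (3.75 ± 0.49), Plaur and the collagenase Mmp13 (3.36 ± 0.63, with a dim aorta mean of 4.02). Their camera adjusted p was 7.04e-08, and adjusted p = 0.134 with an estimated correlation. Of 10 pericyte markers 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.381 with an estimated correlation), with Notch3 (1.52 ± 0.29) and Ndufa4l2 (1.44 ± 0.18) changing most.

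Heart muscle markers fell in 12 of 14 cases (12 adjusted over the list alone), with a median of -3.93 and a camera adjusted p of 2.21e-13 that held with an estimated correlation (0.0215). Behind Myl7 and Myh6 came cardiac troponin I, Tnni3, which fell by 4.81 ± 0.14. Brown adipocyte genes fell in 13 of 14 cases (13 adjusted over the list alone), led by Ucp1, Elovl3, Cidea and Slc27a2, with a median of -4.39. General adipocyte genes fell in 17 of 19 cases (18 adjusted over the list alone), with Dgat2 (-3.65 ± 0.65) and Thrsp (-3.61 ± 0.65), both of triglyceride synthesis, in front (median -2.23). The camera adjusted p was 5.25e-09 for the brown list, with adjusted p = 0.22 with an estimated correlation, and 2.84e-05 for the general list, with adjusted p = 0.606 with an estimated correlation. The brown list mean was 10.1 ± 0.15 (SD) in the aortas and 6.19 ± 1.19 in the tumors. It ranged from 5.13 in tumor 3 to 8.065 in tumor 5, and the general adipocyte list mean reached 11.2 in tumor 5, as in aorta. Fabp4, whose promoter drives the Cre transgene, was measured at 11.7 ± 0.98 in tumors and 12.7 ± 0.06 in aortas. Its decrease (-1.01 ± 0.38, adjusted p = 0.0448) was lost when any of aortas 1 to 4 or tumors 1 to 3 was left out (adjusted p from 0.0565 to 0.0932). The call was also lost after quantile normalization (-0.89, adjusted p = 0.0782), with the trend and robust options (0.054) and with the compared groups alone (0.104). Of the subsets chosen after seeing the data, tumors 5 to 7 alone (0.138) and the arrays without aortas 1 and 3 (0.156) lost it. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, fell in 28 of 29 cases (29 adjusted over the list alone), with a median of -1.76. Sdhd (-2.72 ± 0.16) and Cox5a (-2.43 ± 0.18) fell most. Their camera adjusted p was 5.18e-21, and adjusted p = 0.139 with an estimated correlation. Among tumors, the oxidative phosphorylation list mean was highest in tumor 5 (9.70) and tumor 4 (9.24). The brown list mean was also highest in these tumors (8.065 and 7.72). Brown fat and heart muscle tissue in the aorta samples, considered below, may contribute to this decrease too, which was not tested.

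All 31 measured genes of mitosis and G2/M rose (31 adjusted over the list alone), with a median of 1.90. Cyclin A2, Ccna2, rose by 3.58 ± 0.28, the mitotic kinase Cdk1 by 3.49 ± 0.37, the topoisomerase Top2a by 3.22 ± 0.26 and Mki67 by 2.96 ± 0.25. Aorta means of Ccna2 (4.98) and Top2a (4.83) lay below the median of every array, so dim signal limits these differences. In the DNA replication and G1/S list 26 of 29 genes rose and 0 fell (27 adjusted over the list alone), with the helicase subunit Mcm5 (2.01 ± 0.23) and the polymerase Pole (2.0 ± 0.28, with a dim aorta mean of 5.06) in the lead. These calls (camera adjusted p = 1.23e-23 and 2.25e-12) were lost, with adjusted p = 0.139 and 0.23 with an estimated correlation. The fry test, which does not set a list against the other genes, kept both (fry adjusted p = 8.75e-08 and 1.2e-05). For Pole a second, dimmer probe set differed from aorta by 0.246 (limma adjusted p = 0.219). Ribosomal protein genes rose in 18 of 24 cases (19 adjusted over the list alone; camera adjusted p = 4.42e-06, and adjusted p = 0.314 with an estimated correlation), with Rpl32 at 0.80 ± 0.14 and Rpl3 at 0.79 ± 0.14. The ribosomal list median of 0.42 turned to -0.031 when arrays were centred on the housekeeping list, which shares Rplp0 with it.

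The list of let-7 targets and oncofetal genes, which let-7 microRNAs normally repress, rose in 14 of 25 cases and fell in 3 (14 and 3 adjusted over the list alone), and its call held with an estimated correlation (camera adjusted p = 0.000137 and 0.0215). The largest changes were in Thbs1, in the receptor Acvr1c (-2.0 ± 0.62), in the ribonucleotide reductase subunit Rrm2 (1.38 ± 0.20, with a dim aorta mean of 5.24) and in the repressor Bach1 (1.26 ± 0.11). The Acvr1c call was lost without aorta 4 (adjusted p = 0.0514), with the compared groups alone (0.0546) and with tumors 5 to 7 alone (-0.94, adjusted p = 0.316), and without aortas 1 and 3, also chosen after seeing the data (-2.20, adjusted p = 0.0653). Hmga2, a chromatin protein and classical let-7 target, rose by 0.70 ± 0.19 (adjusted p = 0.00538), a call lost when arrays were centred on the housekeeping list (0.25, adjusted p = 0.177) and with tumors 5 to 7 alone (0.30, adjusted p = 0.211). That subset was chosen after seeing the data, because the title codes of these tumors follow those of the normal tissues, which leaves a batch without a label open. Igf2bp3 had means of 5.77 ± 1.03 (SD) in tumors and 4.93 ± 0.34 in aortas (adjusted p = 0.103, and 0.0472 without tumor 4), and Lin28b, which blocks let-7 maturation, had dim means of 4.23 ± 0.08 and 4.29 ± 0.09 (adjusted p = 0.551; -0.52 and adjusted p = 9.42e-05 when arrays were centred on the housekeeping list). Igf2bp1 and Igf2bp2 were not analysed here. MicroRNA machinery genes rose in 9 of 20 cases and fell in 0 (10 adjusted over the list alone), with the silencing cofactor Tnrc6a at 0.85 ± 0.16 and the Argonaute Ago2 at 0.75 ± 0.10. Their camera adjusted p was 0.00197, and adjusted p = 0.199 with an estimated correlation, and the median of 0.29 became -0.16 when arrays were centred on the housekeeping list. Among 16 imprinted genes 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0114, and adjusted p = 0.267 with an estimated correlation), led by Mest and the zinc finger gene Peg3 (2.51 ± 0.36).

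Macrophage and monocyte markers rose in 21 of 22 cases (21 adjusted over the list alone), with the tetraspan protein Ms4a7 at 3.0 ± 0.27 and the pore-forming protein Mpeg1 at 2.21 ± 0.30. Platelet and megakaryocyte genes rose in 8 of 9 cases (8 adjusted over the list alone), led by the adhesion receptor subunit Gp9 (3.0 ± 0.56) and the platelet chemokine Ppbp (2.39 ± 0.55). Neutrophil markers rose in 9 of 16 cases (9 adjusted over the list alone), with Il1b and the resistin-like gene Retnlg (2.74 ± 0.85) in front, both with dim aorta means (3.98 and 3.72). The Retnlg call was lost with the compared groups alone (adjusted p = 0.0706). Without aortas 1 and 3, a subset chosen after seeing the data, Retnlg (2.66, adjusted p = 0.106) and Ppbp (1.89, adjusted p = 0.0526) missed the threshold. The macrophage, platelet and neutrophil lists had camera adjusted p = 1.19e-12, 0.00185 and 0.00148, and adjusted p = 0.199, 0.478 and 0.23 with an estimated correlation. The platelet list mean ranged from 7.24 in tumor 5 to 10.0 in tumor 7, against 6.34 to 7.33 in the aortas.

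The muscle-lineage genes Myod1 and Pax7 differed from aorta by 0.10 ± 0.22 and 0.10 ± 0.14 (adjusted p = 0.781 and 0.628), and by -0.35 each when arrays were centred on the housekeeping list (adjusted p = 0.152 and 0.0387). Skeletal muscle fibre genes rose in 0 and fell in 3 of 25 cases (0 and 2 adjusted over the list alone), although their median difference was 1.19 and their mean 0.61 (camera adjusted p = 0.462). The fibre list mean ranged from 5.33 in tumor 5 to 9.90 in tumor 2 and from 6.15 to 7.86 among the aortas. Of the 3 fibre genes that fell, myoglobin, Mb (-1.81 ± 0.51), and the titin-binding gene Tcap (-1.49 ± 0.44) fell most, ahead of Eno3. The Tcap call was lost with the compared groups alone (adjusted p = 0.0572). Without aortas 1 and 3, chosen after seeing the data, Mb (-1.85, adjusted p = 0.0589) and Tcap (-1.64, adjusted p = 0.0527) missed the threshold.

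**Figure D2:**
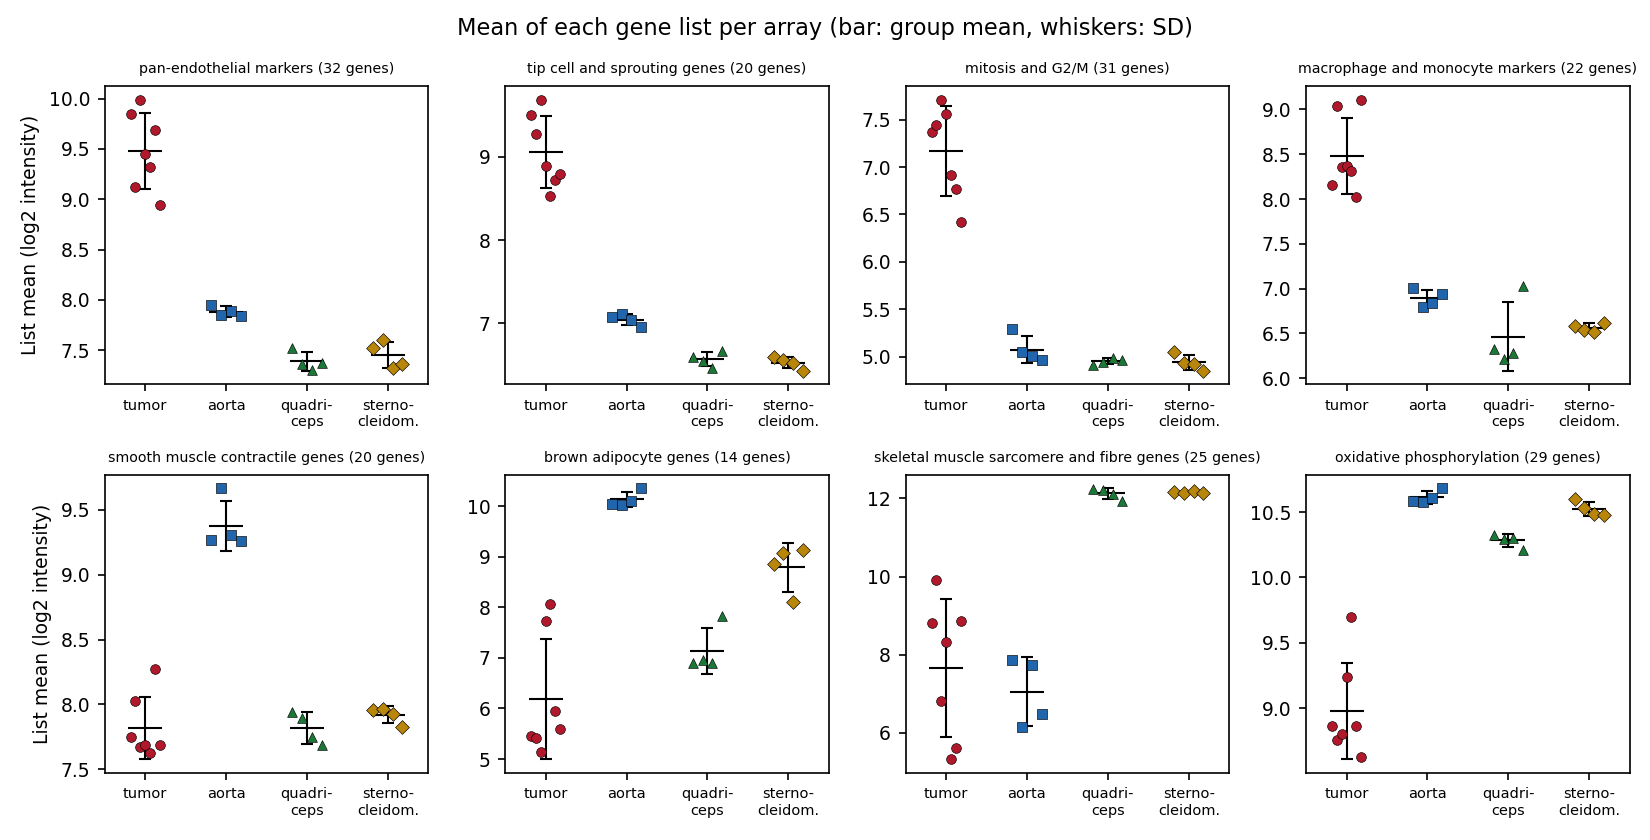
Mean log2 intensity (vertical axes) over the measured genes of 8 lists, 1 point per array, for 7 tumors, 4 aortas, 4 quadriceps and 4 sternocleidomastoid samples (horizontal axes), with group means and SD as bars. Endothelial, sprouting, mitotic and macrophage lists are higher in all 7 tumors than in every normal array, while the skeletal muscle list ranges from 5.33 to 9.90 among tumors.

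In all, 4131 of 22180 genes were higher and 3892 were lower in tumors than in aorta at limma adjusted p under 0.05, of which 1261 and 1308 changed at least 2-fold. The arrays of the groups did not overlap for 5250 genes, where chance gives 0.606% of genes. The share of higher calls was 51.5% but 9.8% when arrays were centred on the housekeeping list (1649 higher and 15227 lower). That list itself had a mean of 10.0 ± 0.10 (SD) in tumors and 9.54 ± 0.03 in aortas, and the centring moved the median of all genes from -0.02 to -0.47.

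The tumor and skeletal muscle comparison asked which genes set the tumors apart from a tissue that surrounds vessels, with both muscles weighted equally. All 25 muscle fibre genes fell, and the myosin kinase gene Mylk4 was about 117-fold lower. Dim signal limits that fold, because the tumor mean of Mylk4 (4.97) lay below the median of every array. Most measured members rose among pan-endothelial markers (31 of 32), sprouting genes (19 of 20), collagen and matrix genes (16 of 19), proteases (19 of 20), mitotic genes (31 of 31) and macrophage markers (21 of 22). These list calls were lost with an estimated correlation (adjusted p = 0.0608 to 0.41 with an estimated correlation). Pecam1 rose 7.19-fold, Thbs1 34.7-fold and Mki67 9.58-fold.

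The largest increases over muscle were in Prnd (5.26 ± 0.26), Thbs1 (5.11 ± 0.25), Mest (4.87 ± 0.23), Timp1 (4.60 ± 0.41), Tnc (4.52 ± 0.35), Ppbp (4.49 ± 0.45), Plvap (4.45 ± 0.16) and Apln (4.43 ± 0.16). A second, dimmer Prnd probe set had a difference of -0.28 (adjusted p = 0.00776). The largest decreases were in Mylk4 (-6.86 ± 0.17), in the growth inhibitor myostatin, Mstn (-6.41 ± 0.22), in the muscle AMP deaminase Ampd1 (-5.82 ± 0.34) and in the glycogen phosphatase subunit Ppp1r3a (-5.80 ± 0.37). Next came the Z-disc protein gene Myoz1 (-5.79 ± 0.51), Ano5 (-5.75 ± 0.25), the mitochondrial creatine kinase Ckmt2 (-5.71 ± 0.38) and Asb15 (-5.60 ± 0.25). As their selection required, all 7 tumors lay beyond all 8 muscles for each of these 16 genes, with adjusted p from 6.8e-16 for Mylk4 to 6.41e-08 for Ppbp. Tumor means of Mylk4, Mstn, Ppp1r3a, Ano5 and Asb15, and muscle means of Apln (5.04) and Prnd (5.33), lay below the median of every array, so their differences and ranks are limited by dim signal.

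All 25 skeletal muscle sarcomere and fibre genes fell (25 adjusted over the list alone), with a median of -4.53, as did all 14 fast fibre genes (14 adjusted over the list alone; median -4.68). Myoz1, the fast myosin Myh4 (-5.59 ± 0.83) and the myosin-binding protein Mybpc2 (-5.48 ± 0.57) were among the lowest. Both calls (camera adjusted p = 5.36e-10 and 3.62e-06) were lost, with adjusted p = 0.41 and 0.368 with an estimated correlation. The fibre list mean was 12.1 ± 0.14 (SD) in quadriceps and 12.2 ± 0.03 in sternocleidomastoid, and 7.66 ± 1.76 in tumors. Myogenic progenitor and embryonic muscle genes fell in 12 of 17 cases (12 adjusted over the list alone), with the regulators Myf6 at -4.48 ± 0.58 and Vgll2 at -3.04 ± 0.27 (camera adjusted p = 0.00146, and adjusted p = 0.41 with an estimated correlation). Myod1 fell by 1.85 ± 0.18 and the satellite cell factor Pax7 by 0.45 ± 0.12. Oxidative phosphorylation genes fell in 28 of 29 cases and rose in 1 (28 and 1 adjusted over the list alone), led by Cox5a (-2.51 ± 0.15) and Ndufs1 (-2.05 ± 0.16), with camera adjusted p = 8.96e-13, and adjusted p = 0.247 with an estimated correlation. Brown adipocyte genes fell in 7 of 14 cases (7 adjusted over the list alone; camera adjusted p = 0.0086, and adjusted p = 0.653 with an estimated correlation), led by Cox7a1 (-4.50 ± 0.40) and Ppargc1a (-3.69 ± 0.48), both of which are also active in muscle. Fabp4 had means of 11.7 ± 0.98 in tumors and 11.9 ± 0.43 in muscle (adjusted p = 0.713), with a difference of -0.72 (adjusted p = 0.0394) when arrays were centred on the housekeeping list and 0.053 after quantile normalization.

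Pan-endothelial markers rose in 31 of 32 cases (31 adjusted over the list alone; median 2.16), led by Plvap, Cd93 (3.20 ± 0.15), Cldn5 (3.01 ± 0.22) and Pecam1 (2.85 ± 0.16), and Cdh5 rose by 2.41 ± 0.10. Their camera adjusted p was 2.2e-17, and adjusted p = 0.139 with an estimated correlation. Tip cell and sprouting genes rose in 19 of 20 cases (20 adjusted over the list alone; median 2.51), with Apln, Aplnr (4.04 ± 0.31) and Plaur (3.69 ± 0.27) highest. Notch pathway genes rose in 14 of 18 and fell in 1 (14 and 1 adjusted over the list alone), led by the ligand Jag1 (2.44 ± 0.15) and Nrarp (2.25 ± 0.16). Camera adjusted p values were 1.48e-11 and 8.65e-06, and adjusted p = 0.0608 and 0.0987 with an estimated correlation. Lymphatic markers rose in 9 of 11 cases and fell in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.134 with an estimated correlation), with the semaphorin receptor Nrp2 at 2.60 ± 0.18 and Flt4 at 2.47 ± 0.19. Angiosarcoma-linked genes rose in 13 of 17 cases (13 adjusted over the list alone; camera adjusted p = 7.73e-05, and adjusted p = 0.0608 with an estimated correlation), with Kdr at 2.77 ± 0.18, Flt4, the phospholipase Plcg1 at 2.04 ± 0.18 and Myc at 1.47 ± 0.26. Cdkn2a had means of 6.41 ± 0.36 in tumors and 6.14 ± 0.23 in muscle (adjusted p = 0.115, and 0.0234 without tumors 2 and 5, chosen after seeing the data), with a difference of -0.29 (adjusted p = 0.0494) when arrays were centred on the housekeeping list.

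Collagen and stromal matrix genes rose in 16 of 19 cases (17 adjusted over the list alone, where 1 fell; median 2.21), led by Tnc and periostin, Postn (3.82 ± 0.25). Elastic matrix genes rose in 9 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone), with Lox at 3.11 ± 0.40 and Mfap5 at 1.90 ± 0.20. Proteases and plasminogen system genes rose in 19 of 20 cases (19 adjusted over the list alone), with Timp1, Plaur, Mmp13 (3.66 ± 0.52, with a dim muscle mean of 3.72) and the membrane metalloproteinase Mmp14 (3.57 ± 0.18). Pericyte markers rose in 9 of 10 cases and fell in 1 (9 and 1 adjusted over the list alone), led by Mcam (3.36 ± 0.17) and the receptor Pdgfrb (2.14 ± 0.15). Angiogenic ligand genes rose in 13 of 21 cases and fell in 4 (13 and 4 adjusted over the list alone), with Apln and Tgfb1 (3.16 ± 0.17) highest. Camera adjusted p values for these lists were 7.33e-09, 0.0114, 1.11e-08, 0.00185 and 0.0113 in that order, and adjusted p = 0.23, 0.446, 0.126, 0.241 and 0.23 with an estimated correlation.

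All 31 mitotic genes rose (31 adjusted over the list alone), among them Cdk1 (3.88 ± 0.30), Top2a (3.84 ± 0.21) and Ccna2 (3.75 ± 0.23). Dim signal limits these differences too, because the muscle means of the 3 genes (5.12, 4.20 and 4.81) lay below the median of every array. In the replication list 27 of 29 genes rose (27 adjusted over the list alone), led by Mcm5 (2.28 ± 0.19) and Mcm6 (1.98 ± 0.20). Camera adjusted p values were 9.22e-18 and 1.75e-10, and adjusted p = 0.22 and 0.273 with an estimated correlation. The let-7 list rose in 17 of 25 cases and fell in 3 (17 and 3 adjusted over the list alone), led by Thbs1 and Rrm2 (1.65 ± 0.16, with a dim muscle mean of 4.96). Its call held with an estimated correlation (camera adjusted p = 0.00139 and 0.0374), although its median of 0.52 became -0.039 when arrays were centred on the housekeeping list. Hmga2 rose by 0.56 ± 0.15, but by that centring its difference was -0.002 and with tumors 5 to 7 alone it was 0.15 (adjusted p = 0.439). Lin28b had means of 4.23 in tumors and 4.46 in muscle (-0.23 ± 0.06, adjusted p = 0.00321), both below the median of every array, so this difference says little about expression. Igf2bp3 had means of 5.77 ± 1.03 in tumors and 5.21 ± 0.17 in muscle (adjusted p = 0.152). Ribosomal protein genes rose in 11 of 24 cases (11 adjusted over the list alone), with Rpl3 at 1.65 ± 0.11 and Rps19 at 0.71 ± 0.11 (0.14 and adjusted p = 0.199 when arrays were centred on the housekeeping list). Their camera adjusted p was 0.0101, and adjusted p = 0.653 with an estimated correlation, and the median of 0.20 became -0.36 when arrays were centred on the housekeeping list.

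Macrophage markers rose in 21 of 22 cases (21 adjusted over the list alone), led by Ms4a7 (3.05 ± 0.22) and Mpeg1 (3.01 ± 0.25, with a dim muscle mean of 5.05). Platelet genes rose in 8 of 9 cases (8 adjusted over the list alone), led by Ppbp and Gp9 (3.65 ± 0.46). Neutrophil genes rose in 10 of 16 and fell in 1 (10 and 1 adjusted over the list alone), led by Il1b (4.40 ± 0.29) and Retnlg (3.04 ± 0.70), both with dim muscle means (4.04 and 3.42). MHC class II genes, of antigen-presenting cells, rose in 6 of 8 cases (6 adjusted over the list alone), led by H2-Ab1 (1.84 ± 0.22) and H2-Eb1 (1.69 ± 0.21). Interferon response genes rose in 11 of 20 cases (11 adjusted over the list alone), led by Rsad2 (2.99 ± 0.29) and Oasl2 (1.53 ± 0.19), with a median of 0.33 that became -0.23 when arrays were centred on the housekeeping list. Camera adjusted p values were 1.48e-11, 0.00163, 0.00582, 0.0117 and 0.0109 in that order, and adjusted p = 0.22, 0.475, 0.273, 0.502 and 0.606 with an estimated correlation.

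**Figure D3:**
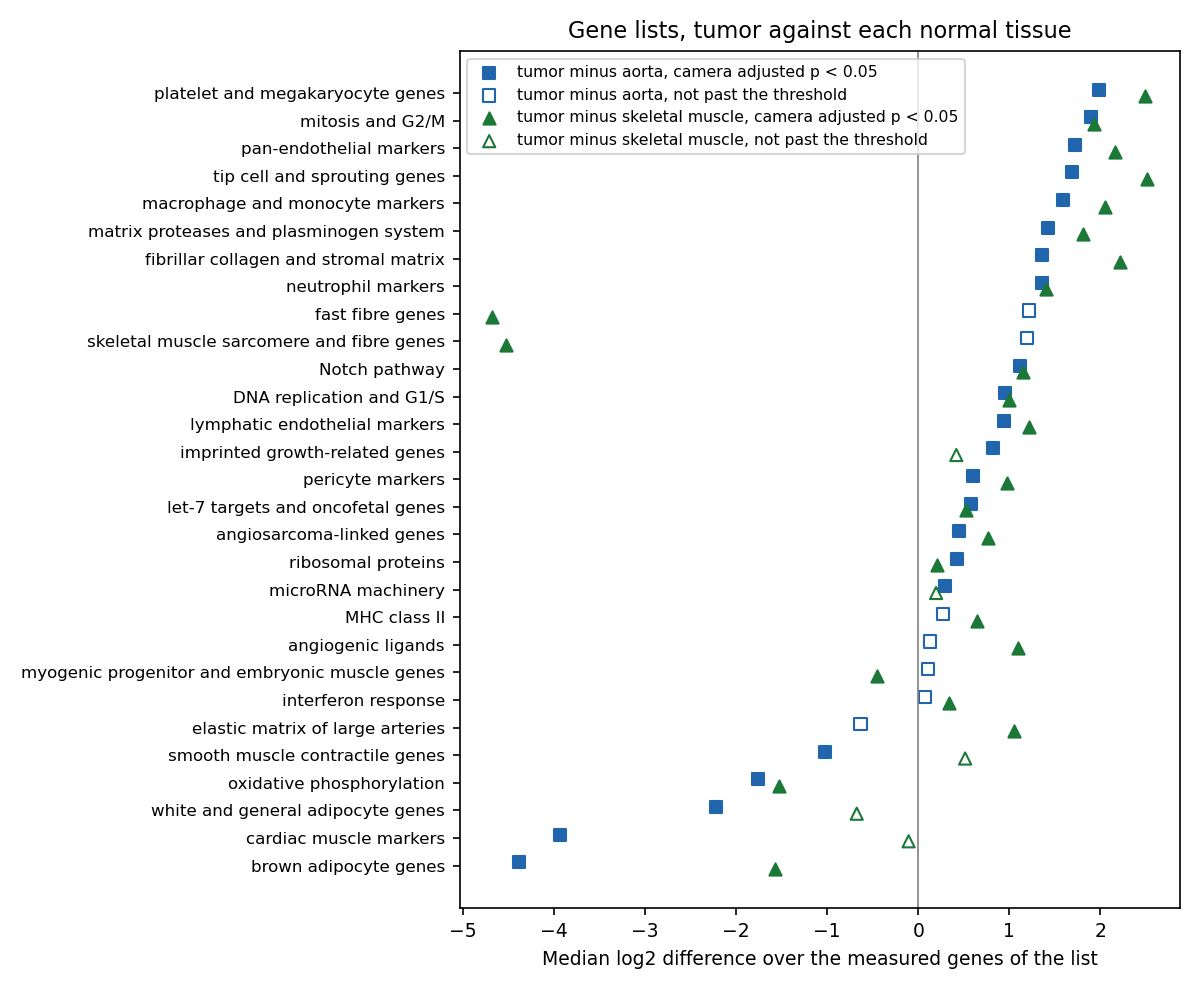
Median log2 difference (horizontal axis) of tumor minus aorta (squares) and tumor minus skeletal muscle (triangles) for the 29 gene lists (vertical axis) called by camera in at least 1 of the comparisons, filled where the preset-correlation adjusted p was under 0.05. Brown adipocyte genes have medians of -4.39 and -1.58, fibre genes 1.19 and -4.53, and pan-endothelial markers 1.72 and 2.16.

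At limma adjusted p under 0.05, 5617 genes were higher and 5691 were lower in tumors than in skeletal muscle, of which 2140 and 1723 changed at least 2-fold. The groups' arrays did not overlap for 6065 genes, where chance gives 0.031% of genes. The share of higher calls was 49.7% but 13.3% when arrays were centred on the housekeeping list (2528 higher and 16479 lower), which moved the median of all genes from -0.04 to -0.60.

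Genes that differed from both normal tissues in the same direction numbered 3322 higher and 2446 lower in tumors, of which 1086 and 645 changed at least 2-fold against each. Genes were ranked by the smaller of their differences from aorta and from muscle. By that rank Prnd, Mest, Il1b, Thbs1, Aplnr and Tfpi2 stood highest, with Tfpi2 at 4.01 ± 0.40 over aorta and 4.29 ± 0.33 over muscle. The respiratory chain subunit Cox7a1 (-4.50 ± 0.48 against aorta and -4.50 ± 0.40 against muscle) had the largest decrease by that rank. Next came the cardiac actin Actc1 (-4.25 ± 0.35 and -4.19 ± 0.29), Mylk4 (-3.99 ± 0.21 and -6.86 ± 0.17), the methyltransferase Inmt (-3.98 ± 0.25 and -3.79 ± 0.21), the mitochondrial coactivator Ppargc1a (-3.83 ± 0.58 and -3.69 ± 0.48) and the respiratory subunit Cox8b (-3.80 ± 0.55 and -3.52 ± 0.46). Dim signal limits the ranks of Prnd, Il1b, Mylk4 and Inmt, which had a group mean below the median of every array. A second, dimmer Prnd probe set was not called higher in tumors (0.105 against aorta and -0.28 against muscle). Cox7a1, Ppargc1a and Cox8b belong to the brown adipocyte list and Actc1 to the heart muscle list. Brown fat and heart muscle tissue in the aorta samples, a candidate explanation considered below, may contribute to their differences from aorta.

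All 7 tumors lay above every aorta and muscle array for 1911 of the genes called higher, and below every one for 1234 of those called lower. The comparisons share the tumor arrays, and 0 genes were called in both in 1 simulated set of unchanged groups. That set held no differences, so its result was fixed in advance and cannot show how much overlap shared tumors add. Independent lists of the observed sizes would share 1046 higher and 999 lower genes. With separate tumors for each comparison, 2501 and 1775 genes were shared when the odd-numbered tumors were set against aorta, and 2237 and 1766 when the even-numbered tumors were. Across genes, which are not independent replicates, the differences correlated at r = 0.626 (0.439 in unchanged simulated data), with a covariance of 0.391 against 0.012 simulated and 0.372 to 0.379 with separate tumors. Another 446 genes were called in opposite directions.

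The quadriceps, a muscle of the hind limb, and the sternocleidomastoid, a muscle of the neck, were compared to give the size of a difference between normal sites. The 6 largest decreases in sternocleidomastoid were in Hoxc10 (-3.54 ± 0.24), Hoxc6 (-3.20 ± 0.38), the actin regulator Mical2 (-2.21 ± 0.31), the growth factor Bmp5 (-2.17 ± 0.27), Hoxc9 (-2.09 ± 0.25) and Mettl11b (-2.01 ± 0.20). Higher in sternocleidomastoid were Elovl3 (2.36 ± 0.51), Zfp385a (2.28 ± 0.18), the sarcomere protein gene Myom3 (2.12 ± 0.37), Agbl1 (2.03 ± 0.29), Smtnl1 (2.0 ± 0.28) and the water channel Aqp4 (1.78 ± 0.16). Sternocleidomastoid means of Hoxc10 (5.02), Hoxc6 (4.52), Hoxc9 (4.77) and Mettl11b (4.73) and the quadriceps mean of Elovl3 (4.17) lay below the median of every array. The differences and ranks of these 5 genes are therefore limited by dim signal.

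Slow fibre genes had a median difference of 0.96, but only the calcium pump Atp2a2 (1.07 ± 0.14) passed the threshold among 15 members (3 adjusted over the list alone), and the call (camera adjusted p = 1.51e-08) was lost, with adjusted p = 0.23 with an estimated correlation and 0.0742 by fry. Brown adipocyte genes had a median of 1.37, with Elovl3 and Slc27a2 (2.20 ± 0.44) the 2 of 14 that rose (10 adjusted over the list alone; camera adjusted p = 1.32e-11, and adjusted p = 0.142 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.23 (camera adjusted p = 6.59e-07, and adjusted p = 0.493 with an estimated correlation). Mast cell markers had a median of 0.20 (camera adjusted p = 0.0241, and adjusted p = 0.337 with an estimated correlation). In both of these lists 0 members passed the threshold (0 adjusted over the list alone), and the largest differences were in Cox8a (0.43 ± 0.23) and Ndufs1 (0.40 ± 0.22), and in Cpa3 (0.87 ± 0.47) and Mcpt4 (0.62 ± 0.67). The brown list mean was 6.89 to 6.95 in quadriceps 1 to 3 but 7.83 in quadriceps 4, and 8.10 to 9.13 in the sternocleidomastoid samples.

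A total of 52 genes were higher and 44 lower in sternocleidomastoid at limma adjusted p under 0.05, of which 30 and 22 changed at least 2-fold, against 1567 genes at an unadjusted p under 0.05. With 1 variance per group 133 and 86 genes were called, and with the compared groups alone 120 and 80. Leaving out 1 array gave 25 to 57 higher and 26 to 51 lower genes, and the calls of Elovl3 and Slc27a2 were lost without quadriceps 1 (adjusted p = 0.125 and 0.108), without quadriceps 2 (0.161 and 0.122) and in further cases among the 8 arrays. The Elovl3 call was also lost when arrays were centred on the housekeeping list (adjusted p = 0.0517) and with the trend and robust options (0.0708), and that of Slc27a2 with the compared groups alone (0.0832).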

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

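The tests of tissue pieces in the aorta samples, of a muscle program in tumor cells, of unprocessed microRNA precursors, of arrays of low Y-linked level alone and of other splits of the samples were chosen only after the results were seen. Brown adipocyte and cardiac genes were far lower in tumors than in aorta, with medians of -4.39 and -3.93, against medians of -0.19 and -0.14 for quadriceps (sternocleidomastoid -2.43 and -0.11), although 6 of the 28 members lay more than 1 below quadriceps too, among them Cox7a1 (-4.43), Actc1 (-4.33), Cox8b (-3.47) and Ppargc1a (-3.46), which averaged 9.16 or more in quadriceps. Over the 28 members the median tumor minus quadriceps difference was -0.172, against -4.32 for aorta, and among the abundant genes Ucp1 averaged 12.8 and Myl7 11.3 in aorta, so brown fat and heart muscle tissue in the aorta samples is a candidate explanation. Pieces of tissue in single aortas are argued against, because the list means varied by at most 0.554 between the 4 aortas. A true difference between aorta and tumor, and between the tissues that surround them, stays open and was not tested.

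Skeletal muscle fibre genes differed between tumors, with list means from 5.33 in tumor 5 to 9.90 in tumor 2. Normal muscle fibres in the tumor samples may explain this. For that explanation, 18 other genes abundant in muscle were to lie as far below normal muscle as the fibre list. The bound written beforehand was a difference under 1 log2 unit in all 7 tumors. Tumor 2 missed it with a difference of 1.521 (medians -3.55 for the other genes and -2.02 for the fibre list). Tumor 6 missed it narrowly, in the opposite direction, with 1.02 (medians -5.895 and -6.918). Differences of these sizes neither meet nor exclude what was written beforehand for this explanation. For a muscle program in the tumor cells, 0 of 17 myogenic progenitor and embryonic muscle genes lay more than 1 log2 unit above every muscle array in tumors 2, 4 and 7, and 1, Igf2, did so in tumor 1. These explanations cannot be told apart for tumors 1, 2, 4 and 7, whose fibre list means lay above every aorta, because 1.521 lies under the bound of 2 that would exclude fibres, while a muscle program at the level of these tumors, below normal muscle, need not bring those genes above it.

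Transcripts of the imprinted Dlk1 to Dio3 region, which carries many microRNA genes, were higher in tumors than in both normal tissues for 8 of 43 probe sets annotated as microRNA and for 6 of 12 others, with 0 lower, against 24 higher and 16 lower of 435 microRNA probe sets elsewhere. The 6 others were the long RNA Rian (1.36 over aorta and 1.35 over muscle) and 5 small nucleolar RNAs. These are not Dicer substrates, so unprocessed precursors left by loss of Dicer would not account for these 6 calls. The 6 calls may themselves reflect sex, as given below, so they do not decide whether precursors add to the microRNA calls. Of the 55 members, 41 were not called higher than both. Among those 41 were the long RNA Meg3 (0.13 and 0.03) and the gene Dio3 (0.20 and 0.17). Unequal numbers of male and female animals cannot be told apart from a tumor difference: 100% of the 14 calls held with the Y-linked gene level as a term, but that term holds 1 shift for all tissues. The arrays of low Y-linked level alone were 5 tumors, 3 aortas and 4 muscles. Among them 0 of the 14 were called higher than both, 5 higher than aorta and 2 higher than muscle. Median differences there were 0.70 from aorta and 0.32 from muscle, against 1.78 and 2.08 among arrays of high level (2 tumors, 1 aorta, 4 muscles). No biological explanation besides unprocessed precursors was tested.

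In each tumor comparison the real grouping gave more called genes than every other split drawn, over 100 splits each. The labels give no animal identity for these samples either. The splits therefore argue only against a random assignment of these arrays to groups. With the compared arrays alone in the fit, for tumor and aorta the real value was 6841 and the highest of the other splits 56. For tumor and muscle they were 11055 and 7559, the latter with tumor 2 exchanged for quadriceps 4. For both tissues, with all 19 arrays in the fit, they were 5768 and 2471. Between the muscles only the real split, 1 of 35, gave as many genes, but the values were 200 and 197. With so small a margin and no animal identity in the labels, this test cannot exclude chance between the muscles. The split with 197 genes had quadriceps 4 exchanged for sternocleidomastoid 3, and why it gave so many genes was not tested.

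Single arrays lay apart from the rest of their group by more than Dixon's critical value for the group's size in 9 of 164 list and group pairs and in 19 of 396 gene and group pairs, where chance gives about 8 and 20. Quadriceps 4 had list means of 7.826 for brown adipocyte, 7.031 for macrophage, 6.27 for interferon response and 7.606 for microRNA machinery genes, and levels of 6.441 for Slc27a2, 12.47 for Fabp4, 11.143 for Cox8a and 9.868 for Ndufs1. Quadriceps 3 had 12.148 for Cox8b. Tumor 2 had 6.819 for the erythroid list, 7.019 for Myod1 and 4.799 for Mstn. Tumor 6 had 7.308 for Hey2, 9.947 for Myh11 and 5.909 for Perp. Tumor 5 had 9.544 for Sdhd and 9.206 for Ndufs1, tumor 4 had 9.059 for Peg3 and tumor 1 had 7.638 for the p53 response list. Aorta 4 had 8.664 for the elastic matrix list, 12.192 for Cidea, 12.31 for Actc1 and 9.088 for Tcap. Aorta 2 had 9.669 for the smooth muscle list and 9.252 for Vegfb, and aorta 1 had 5.598 for Rrm2. In sternocleidomastoid, array 1 had 9.364 for the housekeeping list and array 4 had 7.825 for Plcg1.

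Among the 17824 probe sets without a single gene symbol, which the comparisons did not use, 1027 were higher and 529 lower in tumors than in both normal tissues.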

How the results depend on the processing

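The alternatives with subsets of tumors or aortas were chosen only after the data were seen. Of 186 gene results 156 kept their direction and side of the threshold in every alternative, and of 4874 gene values 4785 were the same, 70 weaker, 16 stronger and 3 reversed. Of 120 list results 64 were the same throughout, and of 600 list values 534 were the same, 53 weaker, 13 stronger and 0 reversed. Centring arrays on the housekeeping list gave 1649 higher and 15227 lower genes against aorta, 2528 and 16479 against muscle, 1345 and 14072 against both, and 29 lower in sternocleidomastoid, and it reversed Pax7 against aorta (-0.352), Cdkn2a against muscle (-0.291) and Hmga2 against muscle (-0.002), because it moved the median of all genes. A 2-fold minimum, which by construction calls fewer genes, gave 1261 and 1308 against aorta, 2140 and 1723 against muscle, 1086 and 645 against both, and 30 and 22 between the muscles. Between the muscles, leaving out dim genes gave 33 and 28, 1 variance per group 133 and 86, the compared groups alone 120 and 80, and a threshold of 0.01 26 and 23. With an estimated correlation 2 lists were called higher and 1 lower against aorta, 1 and 0 against muscle, and 0 higher between the muscles. By the fry test 111 of the 120 list results were the same, 6 stronger and 3 weaker, and 1 list was called higher between the muscles. Centring on the housekeeping list left 3 lists lower against muscle. The cause was not tested for the other changes.

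Leaving out 1 array gave 25 (without quadriceps 2) to 57 (without quadriceps 4) higher genes and 26 (without sternocleidomastoid 2) to 51 (without quadriceps 4) lower genes between the muscles, with 33 higher without quadriceps 1, 27 lower without quadriceps 1, quadriceps 2 or sternocleidomastoid 1 and 28 without quadriceps 3. It gave 3607 to 4275 higher and 3444 to 4002 lower against aorta, and 5435 to 5746 and 5303 to 5622 against muscle. Among named genes, the aorta calls of Lox and Acvr1c were lost without aorta 4 (both adjusted p = 0.0514), that of Cd3g without aorta 1 or 2 or tumor 1, 2 or 3 (0.0533 to 0.148), and Igf2bp3 was called without tumor 4 (0.997, adjusted p = 0.0472). The first-coded 4 tumors gave 4385 and 4094 against aorta, the last-coded 3 gave 3453 and 3056, the tumors without 2 and 5 gave 4396 and 3958, and leaving out aortas 1 and 3 gave 2902 and 3085. Signal over background was not given with the values, so how far dim genes limit the calls is open.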

Other observations

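The test of the let-7 list without its cell-cycle members, and the sex-linked values, were chosen only after the results were seen, while the other lists were fixed beforehand. Response genes of p53 went both ways against aorta, with 7 of 19 rising and 7 falling (7 and 7 adjusted over the list alone; camera adjusted p = 0.514, median 0.16, which became -0.29 when arrays were centred on the housekeeping list). The stress kinase Plk2 rose by 3.60 ± 0.22 and the apoptosis effector Perp fell by 2.50 ± 0.27, a difference limited by dim signal because its tumor mean (5.0) lay below the median of every array. Hypoxia response genes also went both ways, with 8 of 20 rising and 5 falling (10 and 8 adjusted over the list alone; camera adjusted p = 0.67, median 0.19, which became -0.27 with that centring): the mTOR inhibitor Ddit4 rose by 2.11 ± 0.30 and the glucose transporter Slc2a1 by 1.85 ± 0.41, while the hexokinase Hk2 fell by 2.04 ± 0.36. Angiogenic ligands did likewise, with 9 of 21 rising and 6 falling (9 and 7 adjusted over the list alone; camera adjusted p = 0.287, median 0.13, which became -0.32 with that centring): Tgfb1 rose by 2.38 ± 0.21 and Vegfb fell by 1.65 ± 0.25. For Slc2a1 a second, dimmer probe set differed from aorta by 0.084 (limma adjusted p = 0.685).

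Of 13 B and plasma cell markers 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.227), led by the B cell receptor component Cd79a (-1.51 ± 0.41) and the B cell marker Ms4a1 (-1.31 ± 0.33). The B cell list mean was 7.48, 7.06, 6.04 and 6.70 in aortas 1 to 4 against 5.87 to 6.71 in the tumors, so aortas 3 and 4 lay within the tumors' range. Of 19 T and NK cell markers 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.284), where Thy1, which other cell types also carry, rose by 2.25 ± 0.17 and the T cell receptor component Cd3g fell by 1.58 ± 0.55, a call lost without aorta 1 (-1.15) or aorta 2 (-1.12) and with the compared groups alone (adjusted p = 0.0885). The T and NK cell list mean was 6.02, 5.81, 5.13 and 5.33 in aortas 1 to 4 against 5.08 to 5.53 in the tumors. Tumor means of Ms4a1 (4.38) and Cd3g (5.23) lay below the median of every array, so their differences and ranks are limited by dim signal. With tumors 5 to 7 alone, chosen after the data were seen, the calls of Cd79a (-1.23, adjusted p = 0.0653), Ms4a1 (-1.11, adjusted p = 0.0513) and Cd3g (-1.24, adjusted p = 0.166) were lost. Interferon response genes rose in 3 of 20 cases against aorta (2 adjusted over the list alone; camera adjusted p = 0.514). MHC class II genes passed the limma threshold in 0 of 8 cases against aorta (0 adjusted over the list alone; camera adjusted p = 0.683).

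The let-7 list holds 5 genes that are also of the cell cycle (Rrm2, Dna2, Cdc25a, E2f5 and Ccnj). Without them, 10 of the remaining 20 members rose and 3 fell against aorta (median 0.57, camera p = 0.000631, and p = 0.00202 with an estimated correlation). Against muscle 12 rose and 3 fell (median 0.43, camera p = 0.00992, and p = 0.0131 with an estimated correlation). These p-values were not adjusted for other lists.

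Y-linked genes had a high mean in tumors 3 and 7 (8.67 and 8.05), aorta 4 (8.19), quadriceps 3 and 4 (7.82 and 7.92) and sternocleidomastoid 3 and 4 (7.86 and 7.76), and 3.47 to 3.91 in the other arrays. Xist, the RNA that silences an X chromosome, was 8.97 in tumor 3 and 7.77 in tumor 7, against 5.06 to 5.71 in the other arrays with a high Y-linked mean and 11.8 to 12.3 in the other tumors. No explanation of these intermediate values was tested.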
